A study of Mus musculus with 5 samples.

How the data were processed

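RNA-seq libraries were made from CD45-sorted lung cells with a stranded total RNA kit for very small inputs (SMARTer Pico, second version), per the labels' protocols. The deposited table held 14462 rows for 14457 gene symbols, and 5 columns, 1 per library. HISAT2, HTSeq and the genome build mm10 are named, without versions, role or order, per the submitters' processing notes; the annotation, the strand setting and any filter on genes are not given in the sources used here. The table's name speaks of read counts, but its values have 1 decimal and similar medians in every library, so they were read as a scaled signal that the authors made from read counts by a method not given in the sources used here. Low values stepped in near multiples of 1 value per library. Within 0.1 of a step, between 86.1% and 100% of low values per library were whole multiples, and the multiples drifted with height, so whole reads were not recovered and no count-based test was run. The design fixed before the data were examined had assumed raw counts; its written fallback for normalized values was used in its place. Counting error could not be derived from scaled values, and the approximate read numbers in the report rest on the smallest step.

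Libraries were grouped by the treatment label as 3 ctrl and 2 IR. No label gave a batch, a day or a pairing, and replicate numbers follow accession order only. Genes with a value of at least 10 in at least 2 libraries were kept (12777). Values were transformed as log2(value + 1) and fitted with limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a mean trend and robust estimation, with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes kept and called under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes; SE is that of the log2 fold change. All tests were two-sided. With 10 splits of the 5 libraries, an exact permutation test cannot give a p under 0.1.

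Before the data were examined, 42 gene lists were written for leukocyte classes, for cells the sort should remove, for programmes relevant to irradiation and immune suppression, and for library quality. The 38 lists with at least 5 genes tested were compared with all other genes by camera (limma) with a preset correlation of 0.01, and p-values were adjusted over the 38 lists. Of these, 12 passed, and 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05. That setting can raise p without any correlation between genes. For the granule and immature neutrophil list the estimate was -0.0027, under the preset, yet the unadjusted camera p rose from 8.55e-07 to 0.0143. The directional test fry passed 0 lists, with 5 at an unadjusted p under 0.05. Its mixed form, which takes changes in either direction, passed 5. These were the T cell, classical monocyte, type 2 dendritic cell, interferon gamma and immune checkpoint lists. Beside each list that passed camera with the preset correlation stand its genes past the threshold, over all genes and over the list alone. After the all-gene result had been seen, 4 epithelial lists were added, and they are used only in the closing section. Named genes followed a rule fixed before the data were examined. It took the 10 higher and 10 lower genes with the largest fold change among those called, separated between groups and with a mean of at least 1 CPM, leaving out clone names. It also took 22 genes chosen in advance and up to 4 genes per described list, those with the smallest p if called and otherwise those with the highest mean. The rule also selected 1 gene that is not reported here. Symbols were matched to GENCODE vM21 (GRCm38, the assembly of mm10), which held 14101 of them and gave the coordinates. RefSeq names of GRCm38.p6 matched 14 older list symbols. The 5 symbols with 2 rows each were treated as uncertain and not named. Rows of genes that overlap on opposite strands, or that have near-identical copies, may share reads, since the counting is not described.

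The procedure was tested on simulated data made from the means and spread of the ctrl libraries, with 200 of 12777 genes changed in each of 20 simulations. The simulated IR libraries had that same spread. The real IR libraries differed more from each other (median absolute log2 difference 0.600) than pairs of ctrl libraries did (0.383 to 0.508), so the rates may be too favourable. The procedure recovered 26% of 2-fold and 60.5% of 4-fold changes. Among genes with a value of 200 or more it recovered 52.8% and 98.6%. Of its calls 4.62% were false. A list of 16 genes changed 2-fold had an unadjusted camera p under 0.05 in 20 of 20 simulations and an unchanged list in 1. The real lists were held to a p adjusted over 38 lists. Simulated genes varied independently, whereas the estimated correlation within the 12 lists that passed ran from -0.0027 to 0.82. The simulated rate of false lists thus does not carry over to them. Alternatives covered the scaling, the filter, the threshold, the robust estimation, the removal of 98 segment, mitochondrial and haemoglobin genes, each library left out, and, chosen after seeing the data, pseudocounts of 0.5, 5 and 10 and array weights. Where an IR library was left out, the remaining one was assumed to vary like the ctrl libraries. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.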

Results

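RNA was measured in leukocytes from mouse lung, sorted for CD45, a surface protein carried by nearly all leukocytes. The mice bore tumours of MC38, a colon adenocarcinoma cell line of the mouse, and the lungs were taken 3 days after tumour irradiation. The labels give 3 control libraries (ctrl) and 2 libraries from the irradiated group (IR). Nothing in the labels says whether the libraries came from separate animals, so every p-value measures the spread between these samples, which may be technical. The values were read counts per gene that the authors had scaled between libraries. Their totals were 7232126, 7320415 and 7425923 in the ctrl libraries and 7544034 and 8414753 in the IR libraries. Dividing each total by the smallest step between values gave roughly 8030000 to 10230000 reads per library. Spearman correlations between libraries, across genes, lay between 0.891 and 0.956. The first principal component held 41.6% of the variance and set IR replicate 2 (131.5) apart from IR replicate 1 (-6.00) and from the ctrl libraries (-51.9 to -30.5).

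The comparison of IR with ctrl asked how irradiating the tumour altered gene expression in lung leukocytes; the series title names immune suppression and metastasis after radiotherapy. Genes of lung epithelium were among those that rose. Scgb3a2, which encodes a secretoglobin of the airway lining, was 581 ± 49.8 (SD, n = 3) in ctrl and 3366 ± 1230 (SD, n = 2) in IR. The log2 fold change was 2.49 ± 0.23 (SE; limma adjusted p = 1.66e-06). Among neutrophil genes, Csf3r, the receptor for the growth factor G-CSF, rose from 6051 ± 1545 (SD, n = 3) to 14820 ± 5384 (SD, n = 2), a log2 fold change of 1.28 ± 0.24 (SE; limma adjusted p = 0.0152). Among lymphocyte genes, Cd3g, a chain of the T cell receptor complex, fell from 826 ± 64.2 (SD, n = 3) to 371 ± 145.5 (SD, n = 2), with a log2 fold change of -1.21 ± 0.27 (SE; limma adjusted p = 0.0250), and Ebf1, a transcription factor of the B lineage, from 1433 ± 312 to 651 ± 2.48, with a log2 fold change of -1.11 ± 0.23 (SE; limma adjusted p = 0.0152).

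Of 12777 genes tested with limma, 192 changed at an adjusted p under 0.05: 146 were higher in IR and 46 lower, so 76.0% were higher. A further look at size found 112 genes higher and 34 lower by at least 2-fold. In all 192 genes both IR libraries lay beyond all 3 ctrl libraries; among all genes tested, 4023 (31.5%) were separated in this way, where chance gives 20%. Of the 146 higher genes, 115 changed more in IR replicate 2 and 31 more in IR replicate 1. Scaling to library totals shifted the median log2 fold change of all genes by -0.12 and gave 143 higher and 116 lower genes, 55.2% higher. The count was 19 without ctrl replicate 1, 23 without ctrl replicate 2, 95 without ctrl replicate 3, 1006 without IR replicate 1, where the balance turned (447 higher and 559 lower, 44.4% higher), and 96 without IR replicate 2; 15 of the 192 genes, all of them higher in IR, passed in each of these 5 runs.

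**Figure D1:**
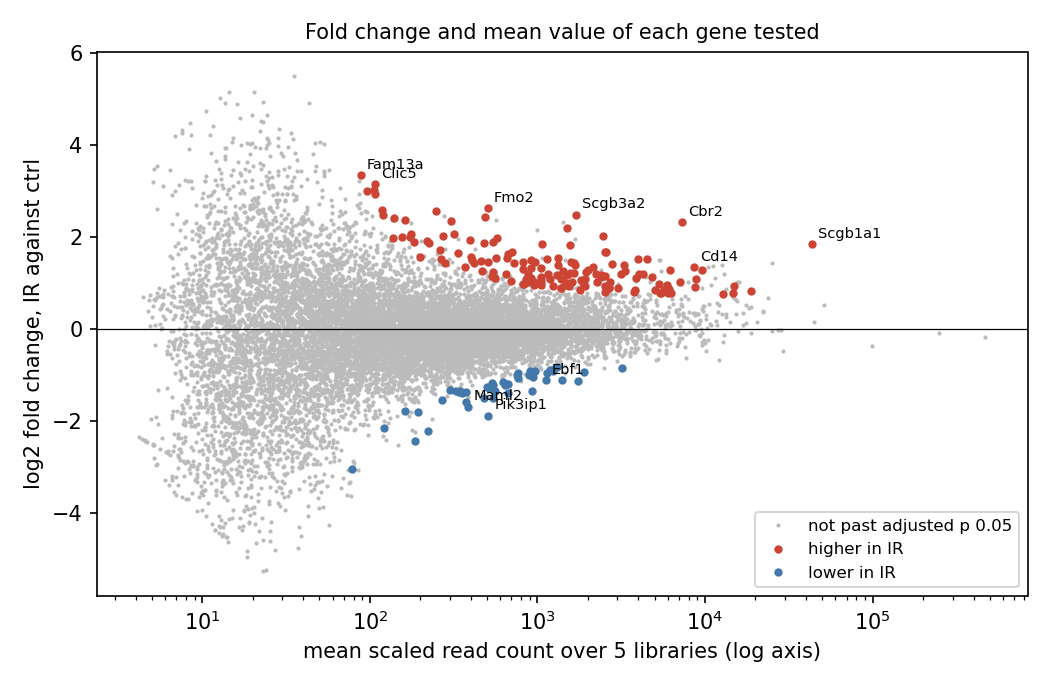
Each point is 1 of the 12777 genes tested; the horizontal log axis is the mean scaled read count over the 5 libraries and the vertical axis the log2 fold change of IR against ctrl. The 146 genes higher in IR and the 46 lower genes are coloured, and Scgb1a1 has the highest mean among the coloured genes.

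The 10 higher genes with the largest fold changes were Fam13a, Clic5, Sult1d1, Gstk1, Ptgr1, Fmo2, Zfand4, Mgat3, Scgb3a2 and Dixdc1, with log2 fold changes from 3.35 for Fam13a to 2.48 for Dixdc1. Fmo2, a flavin monooxygenase abundant in lung (chromosome 1, 162874317 to 162898726), rose from 165 ± 47.9 (SD, n = 3) to 1017 ± 286 (SD, n = 2), a log2 fold change of 2.62 ± 0.33 (SE; limma adjusted p = 6.25e-05). Clic5, an intracellular chloride channel protein (chromosome 17, 44188584 to 44280172), rose from 28.2 ± 15.7 to 226 ± 14.4. Sult1d1, Gstk1 and Ptgr1 encode enzymes that act on small molecules: a sulfotransferase, a glutathione transferase and a reductase of prostaglandins. Their log2 fold changes were 3.02, 3.01 and 2.94. Scgb3a2 is a marker of lung epithelium, and the cells that the other genes' RNA came from were not tested. All of the 10 but Gstk1 and Zfand4 were higher in IR replicate 1 than in IR replicate 2. By contrast, 115 of all 146 higher genes changed more in IR replicate 2. Fmo2 and Scgb3a2 passed with each library left out in turn, and the other 8 genes missed the limma threshold with at least 1 library left out. Without IR replicate 1, these were Fam13a (adjusted p = 0.0842), Sult1d1 (0.0938), Gstk1 (0.0515) and Dixdc1 (0.0685). With robust estimation off, Fam13a (0.0564), Sult1d1 (0.0679), Gstk1 (0.0747) and Zfand4 (0.0701) did not pass, nor did Gstk1 with array weights (0.0922), chosen after seeing the data.

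Lung epithelium was among the classes that the sort should remove, and its 18 markers rose as a list (median log2 fold change 0.92, camera adjusted p = 1.61e-05; adjusted p = 0.625 with an estimated correlation). Among the 18, 2 rose, 0 fell and 16 did not pass; adjusted over the list alone, 6 rose and 1 fell. Both that rose are secretoglobins of club cells: Scgb3a2 (chromosome 18, 43764289 to 43767399) and Scgb1a1 (chromosome 19, 9083636 to 9087958). Scgb1a1 took 0.279% ± 0.0322 (SD, n = 3) of the scaled total in ctrl, 1.38% in IR replicate 1 and 0.606% in IR replicate 2. Its log2 fold change was 1.84 ± 0.24 (SE; limma adjusted p = 0.00306), and it did not pass after scaling to library totals (1.72, adjusted p = 0.0761). The surfactant genes Sftpa1 and Sftpb had log2 fold changes of 0.52 (limma adjusted p = 0.607) and 1.50 (0.0723). The list's median was 1.49 in IR replicate 1 and 0.10 in IR replicate 2, and without IR replicate 1 the list did not pass (adjusted p = 0.204).

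The neutrophil lists were higher in both IR libraries. All 16 mature neutrophil markers had positive fold changes; 5 rose, 0 fell and 11 did not pass, while 14 rose when adjusted over the list alone. Besides Csf3r, Cxcr2, the receptor that draws neutrophils to chemokines, rose with a log2 fold change of 1.66 ± 0.30 (SE; limma adjusted p = 0.0202), Retnlg, a resistin-like protein, with 1.55 ± 0.31 (0.0250), and Trem1, an amplifying receptor of myeloid cells, with 1.28 ± 0.26 (0.0250). The median log2 fold change of the list was 1.32 (camera adjusted p = 6.65e-19; adjusted p = 0.615 with an estimated correlation). Per library it was 0.89 in IR replicate 1 and 1.75 in IR replicate 2, against -0.44 to 0.37 in ctrl. Of the 10 granule and immature neutrophil genes, 2 rose, 0 fell and 8 did not pass; adjusted over the list alone, 4 rose. These 2 were Mmp8, a collagenase stored in granules (1.40 ± 0.24, limma adjusted p = 0.00306), and Pglyrp1, which binds peptidoglycan (1.49 ± 0.29, 0.00886). The median was 1.49 (camera adjusted p = 5.42e-06, and adjusted p = 0.542 with an estimated correlation). The estimate was -0.0027, so correlation between these genes does not account for the larger p. Csf3r, Trem1, Mmp8 and Pglyrp1 did not pass the limma test without ctrl replicate 1 (adjusted p = 0.118, 0.134, 0.0678 and 0.113), and likewise without ctrl replicate 2 (0.0995, 0.116, 0.0517 and 0.111) or IR replicate 2 (0.0656, 0.0921, 0.0584 and 0.0921). Retnlg did not pass without the same 3 libraries (0.0972, 0.116 and 0.211), nor Cxcr2 without IR replicate 2 (0.115). With array weights, chosen after seeing the data, Retnlg (0.437), Cxcr2 (0.0772) and Trem1 (0.0726) did not pass.

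Genes associated with myeloid-derived suppressor cells, immature myeloid cells that restrain T cells, also rose as a list (median log2 fold change 0.83, camera adjusted p = 2.86e-07; adjusted p = 0.625 with an estimated correlation); its median was 0.34 in IR replicate 1 and 1.05 in IR replicate 2. Of 19 tested, 2 rose, 0 fell and 17 did not pass, and 7 rose when adjusted over the list alone. Arg2, a mitochondrial arginase, rose with a log2 fold change of 1.44 ± 0.33 (SE; limma adjusted p = 0.0278), and Cebpb, a transcription factor of myeloid cells, with 0.83 ± 0.18 (0.0223). S100a8, S100a9 and Clec4d are also on the mature neutrophil list. Without them the median was 0.62 (camera adjusted p = 7.68e-05 with the preset correlation), an alternative chosen after seeing the data. Only genes shared with that list were removed, so this cannot separate suppressor cells from neutrophils. Of 13 classical monocyte markers, 3 rose, 0 fell and 10 did not pass (median 0.39, camera adjusted p = 2.05e-05; adjusted p = 0.615 with an estimated correlation); adjusted over the list alone, 4 rose. The median was 0.44 in IR replicate 1 and 0.25 in IR replicate 2, against -0.23 to 0.24 in ctrl, and 0.20 without ctrl replicate 3. The 3 were Hp, the haemoglobin scavenger haptoglobin (1.20 ± 0.19, limma adjusted p = 0.00151), Mgst1, a microsomal glutathione transferase (1.45 ± 0.25, 0.00329), and Cd14, a receptor for bacterial lipopolysaccharide (1.35 ± 0.23, 0.00449). Ly6c2 and Ccr2, further genes of classical monocytes, had log2 fold changes of 0.09 and 0.32 and did not pass (limma adjusted p = 0.907 and 0.542). Hp and Cd14 were higher in IR replicate 2 than in IR replicate 1, and Mgst1 was higher in IR replicate 1. A bulk library does not say which cell an RNA came from, so the rise of Hp, Mgst1 and Cd14 cannot be assigned to monocytes. Arg2 and Cebpb did not pass without any one of ctrl replicate 1 (adjusted p = 0.208 and 0.260), ctrl replicate 2 (0.116 and 0.149), ctrl replicate 3 (0.0706 and 0.0711) or IR replicate 2 (0.288 and 0.127). Cd14 did not pass without ctrl replicate 1 (0.0851) or ctrl replicate 2 (0.0845), nor Hp without ctrl replicate 1 (0.0524). Cebpb did not pass with robust estimation off (0.0775).

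**Figure D2:**
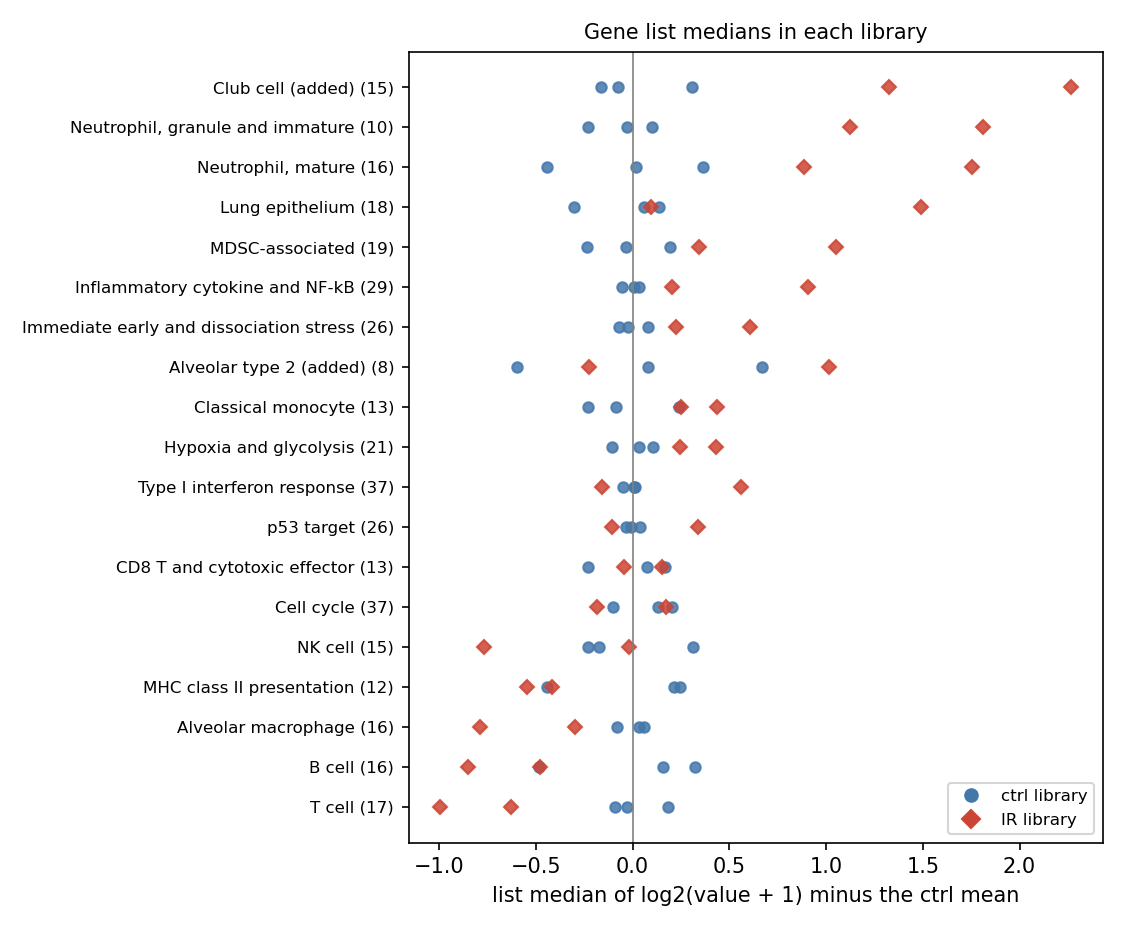
Each row is a gene list with the number of genes tested; the horizontal axis is the list's median of log2(value + 1) minus the mean of the ctrl libraries, with circles for the 3 ctrl and diamonds for the 2 IR libraries. The mature neutrophil list sits at 0.89 and 1.75 in IR, and the T cell list at -0.63 and -0.99. Shown are the lists that passed camera and a selection of others. The club cell and alveolar type 2 lists were added after the all-gene result had been seen.

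The T cell, B cell, alveolar macrophage and MHC class II lists were lower in IR. In IR replicate 1, though, the B cell median (-0.479) and the MHC class II median (-0.419) did not lie below those of ctrl replicate 2 (-0.482 and -0.445). Of 17 T cell genes, 2 fell, 0 rose and 15 did not pass, and 11 fell when adjusted over the list alone (median log2 fold change -0.77, camera adjusted p = 4.43e-08; adjusted p = 0.615 with an estimated correlation). Cd3g was one of those that fell. Of 16 B cell genes, Ebf1 alone fell, 0 rose and 15 did not pass, and 8 fell when adjusted over the list alone (median -0.64, camera adjusted p = 4.95e-07; adjusted p = 0.625 with an estimated correlation). None of 16 alveolar macrophage genes passed singly, and 4 fell when adjusted over the list alone; the list's median was -0.54 (camera adjusted p = 0.000273; adjusted p = 0.625 with an estimated correlation). Plet1, Atp6v0d2, Mrc1 and Chil3 of that list had log2 fold changes of -0.70, -0.53, -0.39 and 0.18. Of 12 genes of MHC class II presentation, 0 passed singly and 3 fell when adjusted over the list alone, with a median of -0.48 (camera adjusted p = 0.000851; adjusted p = 0.625 with an estimated correlation). Cd74, the invariant chain, had a log2 fold change of -0.48 and H2-Ab1 of -0.63 (limma adjusted p = 0.284 and 0.140). The alveolar macrophage median was -0.79 in IR replicate 1 and -0.30 in IR replicate 2, and the list did not pass without IR replicate 1 (adjusted p = 0.279). Cd3g did not pass without IR replicate 2 (limma adjusted p = 0.225) or any one ctrl library (0.116 to 0.205), nor Ebf1 without ctrl replicate 1 (0.155) or ctrl replicate 3 (0.127).

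The 10 lower genes with the largest fold changes were Pik3ip1, Fancm, Maml2, Grap2, Slc30a5, Togaram1, Snx29, Lncpint, Atad2 and Aatf. Pik3ip1, a negative regulator of PI3 kinase signalling (chromosome 11, 3330401 to 3342971), fell from 710 ± 69.2 (SD, n = 3) to 204 ± 99.2 (SD, n = 2), a log2 fold change of -1.88 ± 0.31 (SE; limma adjusted p = 0.00262). Grap2, an adaptor of T cell receptor signalling (chromosome 15, 80572594 to 80652854), fell from 508 ± 13.7 to 172 ± 41.1, a log2 fold change of -1.58 ± 0.31 (0.00886). Lncpint, a long non-coding RNA, had a log2 fold change of -1.39, Fancm, a helicase of the Fanconi anaemia pathway, of -1.80, and Maml2, a coactivator of Notch signalling, of -1.69. Clone or predicted-model names, which the list of largest changes leaves out, made up 8 of the 192 genes, 6 of them lower in IR. Each of the 10 missed the threshold with at least 1 library left out: Pik3ip1 did not pass without ctrl replicate 2 (limma adjusted p = 0.0700), and Grap2 did not pass without ctrl replicate 1 (0.0972), ctrl replicate 2 (0.0877) or ctrl replicate 3 (0.0806). With robust estimation off, Fancm (0.0564), Slc30a5 (0.0503), Atad2 (0.0563) and Aatf (0.0701) did not pass, nor did Aatf with median-ratio factors (0.0505) or, chosen after seeing the data, a pseudocount of 0.5 (0.0536).

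The immediate early, inflammatory and hypoxia lists were higher in IR. Of 26 immediate early and dissociation stress genes, 2 rose, 0 fell and 24 did not pass, and 8 rose when adjusted over the list alone (median log2 fold change 0.42, camera adjusted p = 3.81e-07; adjusted p = 0.625 with an estimated correlation). Ier3, an early response gene, rose from 562 ± 27.6 (SD, n = 3) to 1565 ± 292 (SD, n = 2), a log2 fold change of 1.47 ± 0.23 (SE; limma adjusted p = 0.00151), and Egr1, a zinc finger transcription factor, rose with 0.76 ± 0.19 (0.0391). Among 29 genes of inflammatory cytokines and NF-kB, 0 passed singly and 8 rose when adjusted over the list alone, with a median of 0.68 (camera adjusted p = 0.000100; adjusted p = 0.625 with an estimated correlation). Nfkbia, Il1b, Cxcl2 and Tnfaip3 had log2 fold changes of 1.02, 1.40, 1.11 and 0.13 (limma adjusted p = 0.0580, 0.352, 0.107 and 0.788). Of 21 genes of hypoxia and glycolysis, Slc16a3, a lactate exporter, rose (1.22 ± 0.29, limma adjusted p = 0.0462), 0 fell and 20 did not pass. Adjusted over the list alone, 1 rose and 0 fell. The list was at the threshold (median 0.29, camera adjusted p = 0.0492, and adjusted p = 0.625 with an estimated correlation). Medians in IR replicates 1 and 2 were 0.23 and 0.61 for the immediate early list, 0.20 and 0.91 for the inflammatory list and 0.24 and 0.43 for the hypoxia list. In the same libraries the mature neutrophil median was 0.89 and 1.75, and neutrophils also express Il1b, Cxcl2 and Nfkbia. Without IR replicate 2 the inflammatory list (adjusted p = 0.552) and the hypoxia list (0.161) did not pass; the hypoxia list also did not pass without IR replicate 1 (0.0938) or ctrl replicate 1 (0.165), or after scaling to library totals (0.0834). Egr1 passed with IR replicate 1 left out and with no other library left out, and did not pass with robust estimation off (0.0951). Slc16a3 did not pass without ctrl replicate 1 (0.208), ctrl replicate 2 (0.110) or IR replicate 2 (0.274), nor, in alternatives chosen after seeing the data, with a pseudocount of 0.5 (0.0514) or array weights (0.122).

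**Figure D3:**
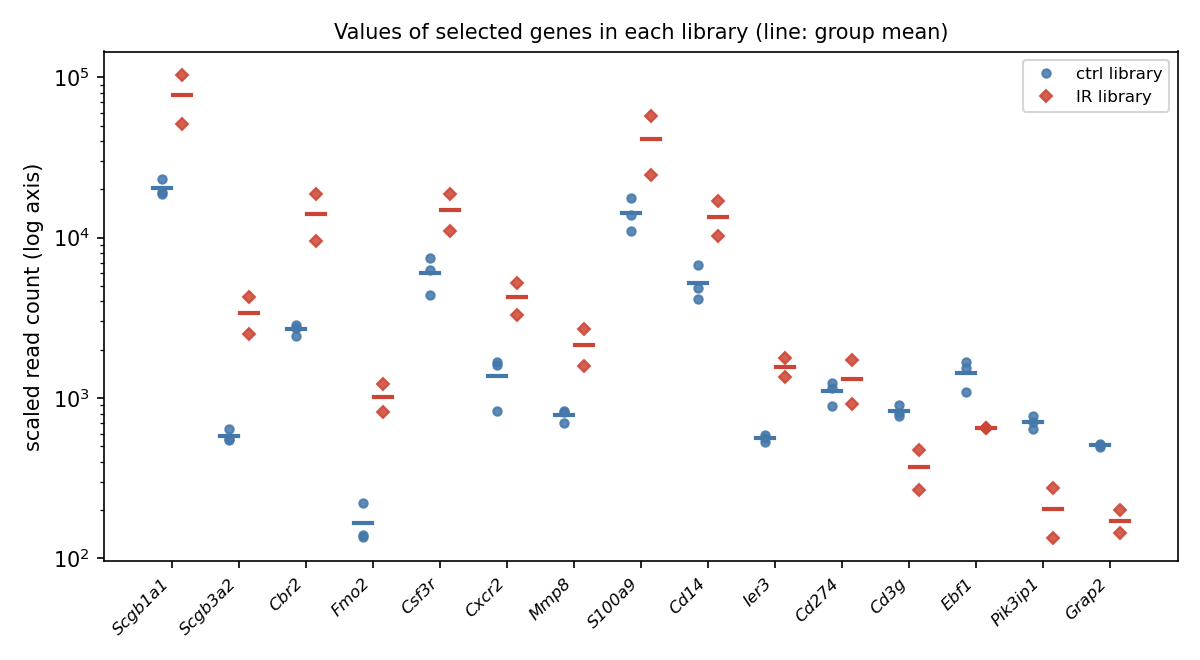
Scaled read counts of 15 genes in each library on a log axis, with circles for the 3 ctrl libraries, diamonds for the 2 IR libraries and a line at each group's mean. Scgb3a2, Cxcr2 and Ier3 lie higher in both IR libraries than in any ctrl library, Cd3g, Ebf1, Pik3ip1 and Grap2 lie lower, and Cd274 overlaps.

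Genes of immune suppression and effector function chosen in advance did not pass the test one by one. Cd274, which encodes the checkpoint ligand PD-L1, was 1100 ± 182 (SD, n = 3) in ctrl and 1319 ± 576 (SD, n = 2) in IR, a log2 fold change of 0.20 ± 0.25 (SE; limma adjusted p = 0.752). Pdcd1lg2, the other ligand of PD-1, had a log2 fold change of 0.73 at low values (21.5 and 32.5). S100a8 and S100a9, the calprotectin subunits of neutrophils, had log2 fold changes of 1.49 ± 0.36 and 1.44 ± 0.35 (limma adjusted p = 0.0902 and 0.104); both passed with the robust estimation turned off (0.0168 and 0.0243), a setting that gave 129 changed genes in place of 192. The neutrophil surface gene Ly6g was low, 13.1 in ctrl and 65.2 in IR, with a log2 fold change of 2.32 (0.309). The suppressive genes Arg1, Il10 and Tgfb1 had log2 fold changes of -1.10, 1.90 and -0.16, and the chemokines Ccl2, Ccl5 and Cxcl10 of 1.03, -0.26 and -0.50. For Foxp3, the factor of regulatory T cells, the log2 fold change was 0.05, for Cd8a -0.47, for Gzmb 0.14, for Ifng -0.29 and for Areg -1.88. Foxp3 (45.2 in ctrl and 39.3 in IR) and Areg (67.4 and 17.15) were also low, with SEs of 0.87 and 0.89. The interferon-induced gene Isg15 had a log2 fold change of 0.47, the p53 target Cdkn1a of 0.37 and the proliferation marker Mki67 of -0.24. Nos2 was listed at 0 in 4 libraries and at 0.7 in ctrl replicate 3 and was not tested. In simulated data with the spread of the ctrl libraries, the same test recovered 26% of genes changed 2-fold and 60.5% of genes changed 4-fold. The IR libraries differed more from each other, so recovery in the real data may be lower.

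The p53 target list (26 genes, median log2 fold change 0.05, camera adjusted p = 0.315) and the cell cycle list (37 genes, median -0.18, 0.396) had 0 genes past the limma test, and neither list passed. The CD8 T and cytotoxic effector list (13 genes) had a median of 0.0013 and a mean of -0.05 (camera adjusted p = 0.960, on the lower side), with Gzma at -0.05 and Prf1 at 0.11. The natural killer cell list (15 genes) had a median of -0.35 (0.243), with Ncr1 at -0.09, and the regulatory T cell list (11 genes) one of 0.73 (0.490). In these 3 lists 0 genes passed the limma test, singly or adjusted over the list alone. Mitochondrial ribosomal RNA took 10.2% ± 0.342 (SD, n = 3) of the scaled total in ctrl and 8.52% ± 1.32 (SD, n = 2) in IR (exact permutation p = 0.1, two-sided, the smallest that 10 splits of 5 libraries allow). The 10 largest genes took 14.8% ± 0.441 in ctrl and 13.6% ± 1.18 in IR (exact permutation p = 0.2).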

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

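Pseudocounts of 0.5, 5 and 10, array weights and the removal of shared genes from a list were chosen after seeing the data. Against 192 genes (146 higher, 46 lower), a threshold of 0.1 gave 386 (268 and 118) and a pseudocount of 10 gave 314 (230 and 84). Library totals gave 116 lower genes, and turning robust estimation off gave 129 genes (107 and 22). With 1 library left out, the counts ran from 19 to 1006 in all, 18 to 447 higher and 1 to 559 lower; the cause was not tested. In all 18 alternatives the 192 genes had the sign they had at first. In each of these genes both IR libraries lay beyond every ctrl library. Leaving out 1 library therefore could not reverse a sign. Nor could another threshold, filter or pseudocount, array weights or turning robust estimation off. Only alternatives that rescaled the libraries could have done so, and for the rest the kept sign is no evidence of stability. The 51 called genes named here are part of the 192 and so kept their sign. Under at least 1 alternative 37 missed the threshold, 34 of them without ctrl replicate 1 and 10 with robust estimation off. Of the 12 lists, 0 passed with an estimated correlation and 0 by fry; 9 to 12 of them passed in the other 10 alternatives run for lists, 9 without IR replicate 1 and 10 without IR replicate 2. All 12 kept their direction in the 12 alternatives run for lists. Genes that had not passed reversed as follows. Under library totals the log2 fold changes were -0.029 for Ly6c2, -0.066 for Foxp3 and -0.014 for Prf1. With a pseudocount of 10 it was -0.0044 for Foxp3, and with array weights -0.0025 for Prf1. With 1 library left out the range was -0.57 to 0.046 for Ccl5, -0.26 to 0.66 for Cd274, -0.023 to 0.38 for Chil3, -1.36 to 0.36 for Cxcl10, -0.57 to 0.51 for Foxp3, -0.26 to 0.16 for Gzma, -0.61 to 0.033 for Ifng, -0.093 to 0.21 for Ly6c2, -0.77 to 0.60 for Ncr1, -0.19 to 0.37 for Prf1, -0.16 to 1.20 for Sftpa1, -2.14 to 0.999 for Sftpc and -0.15 to 0.41 for Tnfaip3. The IR minus ctrl differences in the shares of Scgb1a1, mitochondrial rRNA and the 10 largest genes kept their sign with only the kept rows counted and with each library left out; that of Scgb1a1 was 0.33 percentage points without IR replicate 1 and 1.10 without IR replicate 2, against 0.71. The planned count-based tests, with and without sample quality weights, were not run, because the values are not counts. No paired analysis was possible because the replicate numbers follow accession order.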

Other observations

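All tests of explanations in this part, the 4 epithelial lists and the choice of genes by their stability were made only after the results were seen. Of the 15 genes that passed with each of the 5 libraries left out in turn, Scgb1a1, Scgb3a2, Cbr2, Aldh1a1 and Sec14l3 are markers of club cells. The others were Fmo2, Ier3, Mgst1, Alas1, Epas1, Gsta4, Mtus1, Nfe2, Scnn1a and Selenbp1. The cells that their RNA came from were not tested, so they may include further epithelial genes. Fmo2 (1219 and 814.5) and Mgst1 (1252 and 1097) were higher in IR replicate 1 than in IR replicate 2, as were the club cell markers just named. Ier3 (1358 and 1772) was higher in IR replicate 2. Epas1, the hypoxia-inducible factor 2 alpha, had a log2 fold change of 2.20 ± 0.26 (SE; limma adjusted p = 4.9e-05). Nfe2, a transcription factor of megakaryocytes and granulocytes, had one of 1.89 ± 0.30 (0.00151), and Scnn1a, a subunit of the epithelial sodium channel, one of 1.54 ± 0.27 (0.00329). In the added club cell list, 6 of 15 genes rose, 0 fell and 9 did not pass, with a median of 1.83, 2.27 in IR replicate 1 and 1.33 in IR replicate 2. Cbr2, a carbonyl reductase, rose by a log2 fold change of 2.32 ± 0.23 (limma adjusted p = 1.1e-05), and Aldh1a1, a retinal dehydrogenase, by 2.02 ± 0.22 (1.38e-05). Of the added alveolar type 2, alveolar type 1 and ciliated cell lists, with medians of 0.41, 0.77 and 0.87, Clic5 of the alveolar type 1 list rose and the other 24 genes did not pass. These medians rested on IR replicate 1, where they were 1.02, 1.34 and 2.44, against -0.23, 0.13 and 0.16 in IR replicate 2.

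Among interferon genes, Oasl2 and Oas3, both of the antiviral oligoadenylate synthetase family, rose with log2 fold changes of 1.45 ± 0.29 and 1.18 ± 0.28 (limma adjusted p = 0.0250 and 0.0414), while the other 35 genes of the type I interferon list did not pass. That list had a median of 0.19 (camera adjusted p = 0.119), -0.16 in IR replicate 1 and 0.56 in IR replicate 2; without IR replicate 2, Oasl2 (0.92, limma adjusted p = 0.115) and Oas3 (0.63, 0.364) did not pass, nor did either without ctrl replicate 1 (0.113 and 0.231) or ctrl replicate 2 (0.120 and 0.128). In the interferon gamma list 0 genes of 19 passed, the median was 0.12 and the mean -0.29. Of 22 immune checkpoint genes, Entpd1, which encodes the ectonucleotidase CD39, rose (1.40 ± 0.26, limma adjusted p = 0.00695) and 21 did not pass. Entpd1 did not pass without ctrl replicate 1 (0.0972), ctrl replicate 2 (0.0786) or IR replicate 2 (0.0689). Hdc, which makes histamine and stood on the basophil and mast cell list, rose by 1.53 ± 0.30 (0.0320), and the list's other 5 genes did not pass; Hdc did not pass without ctrl replicate 1 (0.0850), ctrl replicate 2 (0.0963) or IR replicate 2 (0.0868), nor with array weights (0.240). The basophil and mast cell list had a median of 1.28 (camera adjusted p = 0.258), and which cells the Hdc RNA came from was not tested. No dendritic cell list passed camera. The medians were -0.09 for type 1, 0.37 for type 2, -0.24 for mature and -0.02 for plasmacytoid dendritic cells (camera adjusted p = 0.725, 0.655, 0.396 and 0.791). The type 2 list passed the mixed form of fry (adjusted p = 0.0118). Its mean was -0.15, and 2 of its genes fell when adjusted over the list alone. Xist, the RNA of X inactivation, was 6132 ± 1411 (SD, n = 3) in ctrl and 3837 ± 42.6 (SD, n = 2) in IR, a log2 fold change of -0.65 (limma adjusted p = 0.104; 0.0258 after scaling to library totals).

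Club cell genes were higher in both IR libraries although the sort for CD45 should remove epithelium. Carry-over of all lung epithelium alike cannot be ruled out. The alveolar type 2 median lay 1.43 below that of the club cell list (exact permutation p = 0.00382 over 15 and 8 genes, which are not independent), by 1.25 in IR replicate 1 and 1.55 in IR replicate 2. In ctrl the same difference ran from -0.83 to 0.90, and both IR values lay under the ctrl mean plus 2 SD (1.72), a bound set after the values were seen. In IR replicate 1 the ciliated cell median (2.44) was also no lower than that of the club cell list (2.27). The surfactant genes Sftpa1, Sftpb and Sftpc had log2 fold changes of 0.52, 1.50 and -0.57, none past the limma test, and Sftpb, which club cells also make, lay above every ctrl library in both IR libraries. The scaling of the values is argued against, since the lowest median of the club cell list over 4 scalings was 1.71, where scalings moved all genes by at most 0.12. Club cells or their free RNA in the sorted samples remain a candidate source. In both IR libraries 14 of 15 markers lay above every ctrl library, which restates the rise and does not bear on its source. Such a source cannot be told apart from a change inside the sorted cells, because a bulk library does not say which cell an RNA came from. An effect of irradiation on club cells stays open as untested.

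The neutrophil lists were higher and the T and B cell lists lower in IR, although the B cell median in IR replicate 1 (-0.479) did not lie below ctrl replicate 2 (-0.482). A lower share of lymphocytes would raise every other class alike, but the alveolar macrophage median (-0.54) moved the other way and lay 1.86 below the mature neutrophil median. The difference was 1.67 in IR replicate 1 and 2.05 in IR replicate 2, against -0.36 to 0.33 in ctrl and above the ctrl mean plus 2 SD (0.68), a bound set after the values were seen. The alveolar macrophage list was likewise picked after its fall was seen, and 0 of its 16 genes passed the limma test. Its median was -0.79 in IR replicate 1 and -0.30 in IR replicate 2. Among the monocyte, interstitial macrophage and dendritic cell lists, medians ran from -0.28 to 0.39, also under the mature neutrophil median of 1.32. The eosinophil list (5 genes) had a median of 0.08, but the basophil and mast cell list (6 genes) had one of 1.28, near that of neutrophils. A larger share of neutrophils, or higher expression in them, after irradiation may underlie the pattern, and neither was tested. The neutrophil list did not pass with an estimated correlation, so this remains a hypothesis.

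The count of 192 changed genes was reached by 1 of the 10 splits of the 5 libraries into 3 and 2, the real one, and the highest count of the other splits was 0. With 10 splits no share under 0.05 can be reached.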
